A study of Mus musculus with 4 samples.

How the data were processed

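RNA-seq libraries of sorted splenic NK cells of C57BL/6J mice were analysed: DNAM-1+ and DNAM-1- cells from normal spleen (day 0) and from spleen of mice carrying MLL-AF9 AML (day 17), with 1 library for each of the 4 groups, taken from the sample titles and labels. The labels name only the DNAM-1 sort of NK cells, and do not give the other gates, the purity, or the number of mice behind a library. Per the submitters' notes, GFP-positive leukaemia cells were transplanted into unirradiated mice, RNA was extracted with an RNeasy kit, and libraries were sequenced on the BGISEQ-500 platform. The submitters' processing notes name Bowtie2 2.2.5 and RSEM, whose version and role are not given. The sources used here give no genome build or annotation.

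The deposited values are FPKM per the file headers, in 2 decimals, under NCBI Gene numbers, and each file lists only genes above 0. A gene not listed in a library was taken as 0. Of 17723 gene numbers in any library, 17668 matched a symbol in the RefSeq gene table of assembly GRCm38.p6, and 55 did not and were kept without a symbol. The table served for names, biotypes (15844 protein-coding genes) and microRNA lengths alone, and no coordinate was used. Members of gene lists were matched by symbol, or by a synonym that belongs to a single gene. The libraries list 15600, 16161, 15460 and 15595 genes (DNAM-1+ normal, DNAM-1- normal, DNAM-1+ AML, DNAM-1- AML), and 14046 in all 4. Library totals were not used here. Depth was estimated from the smallest FPKM steps of microRNA genes of 55 to 100 nt, of whose values 90.7%, 90.3%, 93.9% and 92.3% lay within 0.1 step of a whole multiple of up to 6 reads, as 9400000, 9100000, 9300000 and 9200000 fragments. At that depth 5 FPKM on a transcript of 2000 nt is about 91 reads in the shallowest library, and the 95% counting interval of a log2 ratio of equal values is 0.42 to either side. This covers counting error only, not the spread between mice. Log2 values correlated between libraries with r = 0.943 (the 2 normal libraries), 0.956 (the 2 AML libraries), 0.982 (the 2 DNAM-1+ libraries) and 0.985 (the 2 DNAM-1- libraries).

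Comparisons, tests, gene lists, cell type markers and alternatives were fixed before the data were examined, except where noted. Each of 4 contrasts (DNAM-1+ against DNAM-1- in each spleen, AML against normal in each subset) is a log2 ratio after adding 1 FPKM to both values. Genes at 5 FPKM or more in the higher library were counted at an absolute log2 ratio of 1 or more. These ratios describe 2 libraries and carry no test. The 2 DNAM-1 contrasts share no library, nor do the 2 AML contrasts, and their agreement was measured by correlation across genes at 5 FPKM or more in any library, and by genes at least 2-fold in both beside the number that independent lists would share. The only test was limma 3.58.1 (R 4.3.3) with its mean-variance trend on log2(FPKM + 1) of all 4 libraries, with subset and spleen as additive terms, 1 residual degree of freedom and 9074 genes, two-sided, called at a Benjamini-Hochberg adjusted p below 0.05. It tests the mean difference over both levels of the other factor against 0. Its residual is the interaction, moderated across genes, so a call does not show that the difference was alike on both levels. The AML coefficient is secondary, because the labels do not say whether the subsets of a spleen came from the same mice. The interaction itself has no residual degrees of freedom and is given as a value. Pairing by mouse was not possible, because no mouse is identified in the labels.

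For each of 24 gene lists and 12 other cell types, the median log2 ratio of members at 1 FPKM or more in any library was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, with random seed 11. The central 95% of random lists is no p-value for mice. limma calls of a list were counted with the adjustment over all genes and, separately, over its members alone. The lists cover NK lineage, activating receptors, inhibitory receptors, cytotoxic genes, cytokines, IL-15 signalling, IL-12, IL-18 and interferon receptors, CD27-positive, CD11b-positive and ILC1 genes, transcription factors, cell cycle, interferon-stimulated, immediate early, NF-kappaB, TGF-beta, exhaustion, glycolysis, oxidative phosphorylation, MYC, ribosomal protein, adhesion, chemokine receptor and apoptosis genes. Tested on simulated data, the limma fit recovered 96% of 100 genes changed 2-fold for the subset and 96% for AML. Of its calls, 9% and 13.4% were unchanged genes. These shares depend on the number of changed genes put in and do not carry over to the real calls. Of 160 simulated list medians, 7 lay outside the central 95% without a shift and all 160 with a log2 shift of 0.5.

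Genes named are Cd226, Ncr1, Klrb1c and Ptprc, then for each contrast the 8 with the highest and the 8 with the lowest log2 ratio at 5 FPKM or more in the higher library, excluding predicted and clone names. The 8 a direction with the largest smaller ratio in both contrasts were named next. So were the 2 to 4 furthest members of each list in the contrast, the 3 most abundant markers of each cell type, and the 8 largest differences of the DNAM-1 contrast between spleens. The 8 protein-coding genes at each end were added after the data were seen. Alternatives were pseudocounts of 0.1 and 5, floors of 1 and 20 FPKM or none, rescaling by median-ratio size factors, by sum (TPM) or by upper quartile, quantile normalization, limma without trend, and leaving out cell type markers. Protein-coding genes alone, and every alternative for the count of differing DNAM-1 contrasts, were added after the data were seen. No scaling moved the median of all genes by more than 0.1 on the log2 scale. TMM was not run, leaving out a library in turn is not possible with 1 per group, and raw reads were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.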

Results

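Natural killer (NK) cells, the innate lymphocytes that kill leukaemia cells without prior priming, were sorted from mouse spleen by their surface DNAM-1, an activating receptor that binds ligands on tumour cells, and their total RNA was sequenced. The 4 libraries form 2 factors: DNAM-1+ or DNAM-1- cells, and normal spleen (day 0) or the spleen at day 17 after transfer of MLL-AF9 acute myeloid leukaemia (AML). Each of the 4 groups holds 1 library, so there are no replicates, no difference between 2 libraries has a replicate check, and no p-value is given for one. The libraries list 15600 (DNAM-1+ normal), 16161 (DNAM-1- normal), 15460 (DNAM-1+ AML) and 15595 (DNAM-1- AML) genes above 0, and 17723 genes in any library. Their depth, estimated from the smallest steps of microRNA values, was 9400000, 9100000, 9300000 and 9200000 fragments. All levels are the deposited FPKM, and each log2 ratio is taken after adding 1 to both values, which understates the difference of low genes.

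The sort shows in the marker genes. Cd226 (NCBI Gene 225825), the gene of DNAM-1, was at 38.6 FPKM in DNAM-1+ and 0.45 in DNAM-1- cells of normal spleen, and at 36.1 and 0.58 in AML spleen. The NK receptor genes Ncr1 (17086) and Klrb1c (17059), which encode NKp46 and NK1.1, were abundant in every library. In the order DNAM-1+ normal, DNAM-1- normal, DNAM-1+ AML and DNAM-1- AML, Ncr1 was at 573, 383, 597 and 423 FPKM and Klrb1c at 369.7, 318, 422 and 379. The pan-leukocyte gene Ptprc (19264) was at 723, 709, 732 and 755, and its log2 ratio lay between -0.04 and 0.09 in all 4 contrasts.

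In normal spleen, DNAM-1+ cells had more RNA of the interleukin-7 receptor Il7r (16197; 38.5 against 2.06 FPKM), of Thy1 (21838; 251 against 69.1), of the receptor genes Cd160 (54215; 63.8 against 22.7) and Klrb1b (80782; 178 against 51.4), and of the proliferation gene Mki67 (17345; 63.2 against 22.7). DNAM-1- cells had more RNA of the Ly49 receptor gene Klra4 (16635; 667 against 295), whose close family members can share reads, so that its own value is uncertain. DNAM-1- cells also had far more RNA of monocyte and B cell genes, among them Lyz2 (17105; 239 against 29.3 FPKM) and Cd79a (12518; 395 against 73). Of 8915 genes at 5 FPKM or more in the higher library, 114 were at least 2-fold higher and 354 at least 2-fold lower in DNAM-1+ cells, of which 93 and 323 were protein-coding. Protein-coding genes were counted and ranked apart only after the data had been seen, because microRNA and small nucleolar RNA genes of few reads filled the ends of the ranking.

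The protein-coding genes with the highest log2 ratios in normal spleen, after Cd226 (4.77) and Il7r (3.69), were Podnl1 (2.57), Apol7b (2.31), Cd200r1 (1.97), Acpp (1.93), Cd3e (1.90) and Gzmc (1.89). Cd200r1 and Gzmc, a receptor and a granzyme, were low even in DNAM-1+ cells, at 5.31 and 5.89 FPKM. The lowest were Ifitm3 (-3.52), Ace (-3.47), Ear2 (-3.47), Nupr1 (-3.45), Ifitm2 (-3.32), Apoc2 (-3.09), Apoe (-3.07) and Fabp4 (-3.05). Ace is known from non-classical monocytes and Apoe from macrophages. Ifitm2 and Ifitm3 are close paralogs that can share reads. Over all gene types, 5 of the 8 highest and 3 of the 8 lowest named genes were microRNA or small nucleolar RNA genes (among the first Mir719, Mir7036b, Mir6916, Mir6935 and Mir1306; among the second Mir7213, Snord38a and Mir5132), each listed at 0 in the lower library and resting on few reads. The transcribed pseudogene Atp6v0c-ps2, at 8.33 FPKM in DNAM-1+ cells, was also listed at 0 in the lower library.

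In AML spleen, Il7r was at 38.6 FPKM in DNAM-1+ and 2.1 in DNAM-1- cells, Thy1 at 228 and 72, Cd160 at 61.4 and 24.5, Klrb1b at 196 and 63.6, and Mki67 at 36.3 and 16.8. Klra4 was at 646 FPKM in DNAM-1- against 277 in DNAM-1+ cells, Lyz2 at 254 against 41.9, and Cd79a at 399.7 against 88. The plasma cell gene Jchain (16069) was at 206 FPKM in DNAM-1- and 18.2 in DNAM-1+ cells. Of 8839 genes, 79 were at least 2-fold higher and 282 at least 2-fold lower in DNAM-1+ cells, of which 55 and 259 were protein-coding.

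In AML spleen the protein-coding genes with the highest log2 ratios after Cd226 (4.55) and Il7r (3.68) were Apol7b (3.38, listed at 0 in DNAM-1- cells), Podnl1 (11.4 against 0.54 FPKM), Tgtp1 (2.49), Cd200r1 (2.25), Acpp (2.19) and Cd3e (2.14). The lowest were Fabp4 (-3.79), Jchain (-3.43), Krt80 (-3.09), Ace (7.44 against 66.6 FPKM), Fcgr4 (-2.98), Treml4 (-2.79), Nupr1 (-2.79) and Ear2 (-2.79). Fcgr4, Treml4 and Ace are known from the non-classical monocyte. Over all gene types, 5 of the 8 highest (Mir546, Mir7115, Snord65, Mir7050 and Mir7090) and 1 of the 8 lowest (Mir3572) were small RNA genes, and the pseudogene Ubb-ps was listed at 0 in DNAM-1+ cells against 15.5 FPKM in DNAM-1- cells.

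The DNAM-1 contrasts of the 2 spleens share no library. Their log2 ratios correlated across 9074 genes with Pearson's r = 0.74 and Spearman's rho = 0.61 (genes are not independent replicates), and over protein-coding genes r was 0.895. In both spleens 53 genes were at least 2-fold higher in DNAM-1+ cells, against 1.18 for independent lists, 272 were at least 2-fold lower, against 12.2, and 15 went in opposite directions. Among protein-coding genes these counts were 49, 261 and 0. Beside those already named, Trat1, a T cell receptor associated gene, was higher in both (log2 ratios 1.77 and 1.95). limma, fitted to all 4 libraries with the spleen as a block, tested the mean subset difference of the 2 spleens against 0. Of 9074 genes, 667 rose and 760 fell in DNAM-1+ relative to DNAM-1- cells at an adjusted p below 0.05. A call does not show that the difference was alike in both spleens: Cdk1 was called with log2 ratios of 1.79 in normal and 0.65 in AML spleen. Without the mean-variance trend 321 rose and 561 fell, and 826 of the 1427 calls were shared; with a floor of 20 FPKM 523 rose and 434 fell. Il7r rose by 3.68 on the log2 scale (SE 0.08, limma adjusted p = 2.21e-05, higher in 2 of 2 spleens), Klrb1b by 1.69 (SE 0.07, adjusted p = 3.67e-05) and Thy1 by 1.75 (SE 0.07, adjusted p = 3.72e-05). With 1 residual degree of freedom the limma spread is borrowed across genes. On simulated data 9% of the calls for the subset and 13.4% of those for AML were unchanged genes, above the nominal 5%. These shares depend on the 100 genes changed 2-fold and 100 changed 4-fold that were put in for each coefficient. They do not carry over to the real fits, such as the 32 calls for AML, and the simulated noise held no spread between mice.

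**Figure D1:**
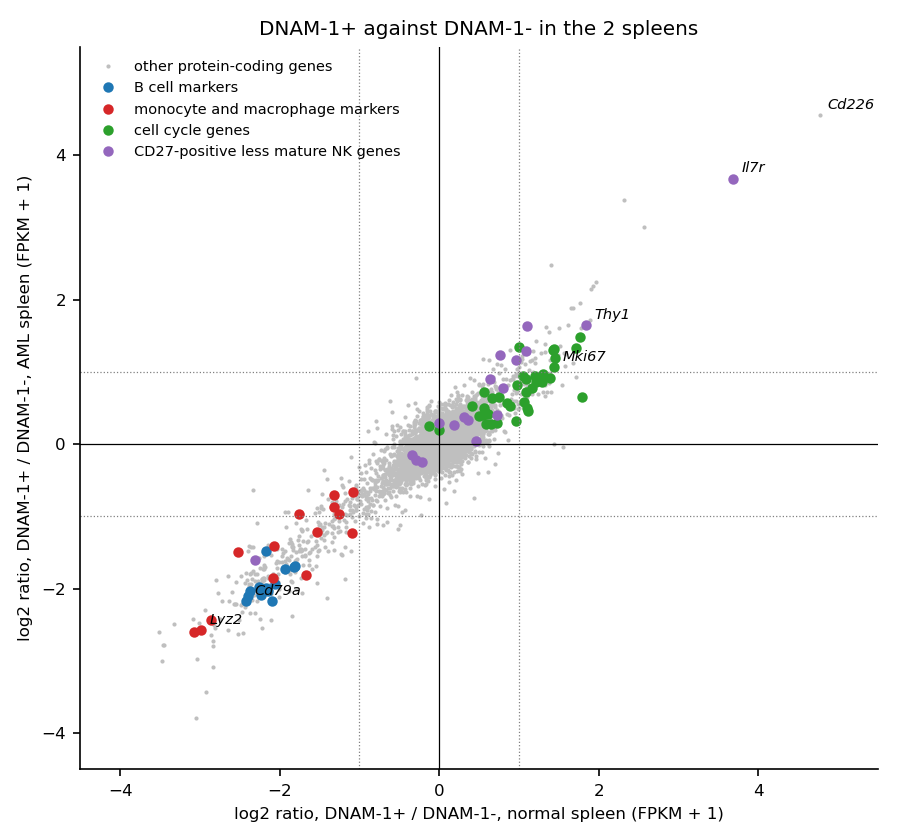
Log2 ratio of DNAM-1+ to DNAM-1- cells (FPKM + 1) in normal spleen (horizontal axis) and AML spleen (vertical axis), for protein-coding genes at 5 FPKM or more in any library; each point is a gene, coloured by gene list, and dotted lines mark a log2 ratio of -1 and 1. Cd226 lies at 4.77 and 4.55, Il7r at 3.69 and 3.68, and all 13 B cell markers lie below -1 in both spleens.

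Genes of the less mature, CD27-positive NK stage were higher in DNAM-1+ cells. The list's median log2 ratio was 0.69 in normal and 0.59 in AML spleen (both outside the central 95% of random lists of like expression), and 11 of 18 tested members rose while 2 fell (limma over all genes; 12 and 4 adjusted over the list alone). Beside Il7r and Thy1, the chemokine receptor gene Cxcr3 (12766) rose, at 41 against 18.5 FPKM in normal and 45 against 13.8 in AML spleen (limma adjusted p = 0.000915). Tcf7, a transcription factor of early lymphoid cells, rose too (173 against 111 and 185 against 98.7). Ccr7 fell, at 2.99 against 18.8 and 4.51 against 15.7 FPKM, and B cells, whose markers also fell (below), are known to express it. The T cell markers, with medians of 0.66 and 0.44, moved with this list. The ILC1 and tissue residency genes had medians of 1.09 (0.48 with a pseudocount of 5) and 0.77, with 7 of 12 tested members rising and 2 falling (7 and 2 adjusted over the list alone). Among them Il7r, Cd200r1, the collagen-binding integrin gene Itga1 (5.36 against 1.13 and 5.34 against 1.99) and the death ligand gene Tnfsf10 (9.92 against 3.2 and 11.5 against 3.23) rose, and Ccr6 fell (1.71 against 10.7 and 2.98 against 10.5).

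Cell cycle genes were higher in DNAM-1+ cells of both spleens. The median log2 ratio of 41 genes was 1.05 in normal and 0.65 in AML spleen, 32 of 38 tested members rose and 0 fell (36 and 0 adjusted over the list alone), beside higher T cell markers (medians 0.66 and 0.44) and lower B cell (-2.17 and -1.99) and monocyte markers (-1.32 and -1.10). Rrm2, needed for DNA synthesis, was at 30.2 against 8.13 FPKM in normal and 20.5 against 6.68 in AML spleen (limma adjusted p = 0.000124). The mitotic genes Top2a (52.6 against 18.6 and 34.5 against 14.5), Birc5 (25 against 6.93 and 14.8 against 5.28) and Cdk1 (8.01 against 1.61 and 4.4 against 2.44) also rose.

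NK lineage genes had medians of 0.20 and 0.15, and 5 of 18 members rose and 0 fell (8 and 0 adjusted over the list alone). The furthest was Cd7 (12516), a surface protein of T and NK cells, at 509.8 against 209 and 616 against 255 FPKM (limma adjusted p = 5.21e-05). Ncr1 and Tbx21, the gene of the transcription factor T-bet, rose as well (Tbx21 218 against 169 and 194 against 147). Activating and costimulatory receptors had medians of 0.26 and 0.21, with 12 of 23 rising and 3 falling (14 and 4 adjusted over the list alone). The 12 include Cd226, on whose product the cells were sorted. Both lists rose beside higher T cell markers (medians 0.66 and 0.44) and lower B cell and monocyte markers. Cd160 and Icos (5.6 against 2.12 and 5.81 against 2.17) rose, and Klra4 fell (limma adjusted p = 6.74e-05). Inhibitory receptors and checkpoints went both ways, with medians of 0.15 and -0.02, 5 of 20 rising and 6 falling (7 and 7 adjusted over the list alone). Klrb1b and Cd200r1 rose, Siglecg, known also from B cells, fell (8.06 against 43.9 and 10.4 against 38.4), and Havcr2, the gene of TIM-3, fell (1.41 against 7.78 and 1.92 against 6.46). The CD11b-positive mature NK genes had medians of -0.11 in both spleens, with 1 of 22 rising and 5 falling (1 and 7 adjusted over the list alone), beside the far lower B cell markers (medians -2.17 and -1.99) and monocyte markers (-1.32 and -1.10). The protease gene Cma1 fell (119 against 168 and 129.5 against 198), Irf8, which B cells and monocytes are also known to express, fell (185 against 248 and 186 against 238), and Gata3 rose (36.2 against 26.6 and 36.2 against 27.9).

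Cytotoxic granule and death ligand genes had medians of 0.07 and 0.06, with 5 of 22 rising and 2 falling (6 and 3 adjusted over the list alone). Gzmc and Tnfsf10 rose, and so did Gzmk (16.9 against 9.81 and 14.2 against 10.4). The perforin gene Prf1 was at 498, 528, 571 and 619.9 FPKM and Gzma at 3885, 3209.5, 3947 and 4072 in the order given above. Cytokines and chemokines had medians of -0.07 and 0.18, and 4 of 11 rose and 1 fell (5 and 3 adjusted over the list alone). Xcl1 (16963), which attracts cross-presenting dendritic cells, rose (284 against 167 and 382 against 162, limma adjusted p = 0.00211). Flt3l, a growth factor of those cells, rose (51.3 against 32.4 and 55.6 against 33.9), and Ccl9 fell (4.41 against 10.6 and 6.04 against 13.2).

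In IL-15 and common gamma chain signalling (medians -0.01 and 0.11; 6 of 23 rising and 3 falling, the same counts adjusted over the list alone), Il7r and Socs2 rose (Socs2 7.27 against 1.63 and 6.55 against 1.05) and Il21r fell (15.2 against 32.6 and 16.2 against 26.3). In IL-12, IL-18 and interferon receptors and signalling (medians 0.11 and 0.06; 5 of 18 rising and 2 falling; 7 and 3 adjusted over the list alone), Il12rb1 rose (22.9 against 13.8 and 22 against 12.2) and Ifngr2 fell (6.39 against 20.4 and 6.59 against 21.1). Among NK transcription factors (medians 0.11 and 0.05), 7 of 27 rose and 6 fell (9 and 8 adjusted over the list alone). Id2, required for NK development, rose (425 against 271 and 460.4 against 318), and Ikzf2 rose (5.7 against 1.1 and 5.82 against 0.84). Irf4, also among the plasma cell markers, fell (3.33 against 13.4 and 3.83 against 12.2). Adhesion and DNAM-1 pathway genes had medians of 0.04 and 0.12, with 6 of 24 rising and 2 falling (8 and 4 adjusted over the list alone). Itgb7 rose (174 against 111 and 180.2 against 123), as did Cd96, whose product shares a ligand with DNAM-1 (45.2 against 32.3 and 52 against 35.6). The competing inhibitory receptor gene Tigit fell (24.1 against 30.9 and 19.8 against 27.2), and so did the kinase gene Syk (93.5 against 137 and 89.3 against 131). These falls stand beside the far lower B cell markers (medians -2.17 and -1.99) and monocyte markers (-1.32 and -1.10). The cell source of genes that fell in DNAM-1+ cells, in these and the other lists, was not tested gene by gene.

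Immediate early and stress genes had medians of -0.44 in normal and -0.14 in AML spleen, and 1 of 33 rose and 13 fell in DNAM-1+ cells (1 and 17 adjusted over the list alone), beside the B cell markers (medians -2.17 and -1.99) and monocyte markers (-1.32 and -1.10). Klf4 (3.71 against 20.6 and 5.79 against 21), Atf3 (5.21 against 16.7 and 5.22 against 10.9), Nr4a1 (65.1 against 167 and 72.5 against 127) and Fos (18.3 against 49.9 and 43.8 against 74.9) fell. NF-kappaB response genes had medians of -0.31 and -0.06, with 0 of 21 rising and 6 falling (1 and 8 adjusted over the list alone), among the latter Cd83 (4.31 against 17.5 and 4.93 against 11.7) and Rel (11.5 against 19.9 and 11.4 against 18.8). Chemokine receptors had medians of -0.24 and -0.14, with 4 of 16 rising and 6 falling (5 and 9 adjusted over the list alone). Cxcr5, a B cell homing receptor, fell (6.89 against 27.2 and 6.52 against 24.2), and so did Cxcr4 (41.8 against 64.5 and 62 against 86). Interferon-stimulated genes had medians of 0.04 and 0.03, with 6 of 39 rising and 7 falling (6 and 8 adjusted over the list alone). Ly6a fell (9.7 against 48.2 and 10.3 against 32.1), as did Oas2 (2 against 15.1 and 1.01 against 5.91). Exhaustion-associated genes had medians of 0.12 and 0.00, with 7 of 17 rising and 6 falling (8 and 6 adjusted over the list alone). Lag3 rose (8.26 against 5.02 and 12.8 against 5.14). In apoptosis genes (medians -0.08 and 0.00; 2 of 24 rising and 4 falling; 2 and 5 adjusted over the list alone), Pmaip1 fell (5.06 against 18.2 and 6.35 against 15.5).

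Glycolysis genes had medians of 0.12 in both spleens (3 of 17 rising and 0 falling; 5 and 1 adjusted over the list alone), with Ldha at 170.0 against 137 and 172 against 118 FPKM. Oxidative phosphorylation genes had medians of 0.05 and 0.14 (2 of 35 rising and 0 falling; 0 and 0 adjusted over the list alone), MYC and mTORC1 growth genes 0.06 and 0.08 (3 of 29 and 1; 3 and 2 over the list alone), and cytosolic ribosomal protein genes -0.01 and 0.01 (2 of 42 and 0; 1 and 0 over the list alone). TGF-beta signalling genes had medians of -0.07 and -0.03, with 1 of 15 rising and 1 falling over all genes and adjusted over the list alone: Itga1 rose and Tgif1 fell (21.2 against 31.3 and 17.8 against 26.5).

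All 13 measured B cell markers fell in DNAM-1+ cells and were at least 2-fold lower in both spleens (medians -2.17 and -1.99), beside Cd79a with Cd79b at 38.1 against 176 and 41.9 against 169 FPKM and Cd22 at 31.3 against 113 and 29.7 against 98.5. All 14 tested monocyte and macrophage markers fell (medians -1.32 and -1.10), with Apoe at 38.8 against 334 and 43 against 266 and Csf1r at 7.31 against 59.7 and 9.84 against 57.6. Dendritic cell markers had medians of -0.68 and -0.55 (-1.68 and -1.51 over members at 5 FPKM or more), and 6 of 8 tested fell. The most abundant, Cd74 (328 against 1458 and 391 against 1385), H2-Ab1 (119 against 556 and 149.8 against 542) and H2-Aa (84.1 against 474 and 127 against 454), are also expressed by B cells. Plasma cell markers had medians of -1.28 and -1.35 (-2.49 and -2.09 with a pseudocount of 0.1, -0.44 and -0.54 with 5), and 4 of 5 tested fell, among them Mzb1 (3.59 against 29.4 and 5.93 against 30.1) and Xbp1 (33.7 against 43.5 and 29 against 43). Neutrophil markers had medians of -0.78 and -0.80, and 7 of 8 tested fell, among them S100a9 (42.9 against 68.3 and 23.7 against 51.5) and S100a8 (18.9 against 36.1 and 15.2 against 26.2), while Cxcr2 was at 45.5, 41.3, 40.4 and 43.7 FPKM.

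T cell markers went the other way, with medians of 0.66 and 0.44, and 5 of 6 tested rose and 0 fell in DNAM-1+ cells (5 and 1 adjusted over the list alone). The other, Cd8b1, was lower, at 2.28 against 5.32 FPKM in normal and 0.67 against 2.11 in AML spleen. Cd3g was at 32.4 against 9.87 FPKM in normal and 32.4 against 9.66 in AML spleen, Cd3e at 9.22 against 1.74 and 8.95 against 1.25, Cd28 at 14.7 against 8.04 and 13.7 against 7.42, and Lat, which NK cells also use, at 56.7 against 42.8 and 63.9 against 50.4. Cd4 was at 1.29, 1.3, 1.38 and 0.75 FPKM and Cd8a at 3.7, 2.17, 2.88 and 2.92 (both named after their values were seen). Erythroid markers had medians of -0.36 and 0.04, with Car2 at 136 against 53.4 and 131 against 53.4, Hba-a1 at 6.41, 9.31, 6.84 and 11.1 FPKM and Tfrc at 5.81, 7.16, 5.22 and 5.07. Leukaemia and myeloid progenitor markers had medians of 0.01 and -0.15. Of these, Kit (17.9 against 7.86 and 25.3 against 9.78) rose, Mef2c (7.66 against 22.5 and 7.68 against 19.8) fell, and Gfi1 was at 21.8, 21.4, 19.2 and 18.4. The 4 measured ILC2 and ILC3 markers, with medians of 0.29 and 0.31, include Ncr1, Klrg1 and Gata3, which NK cells also express, and Ncr1 and Gata3 rose. Platelet, mast cell and stromal markers had 1 measured member each: Gp1bb (2.56, 3.4, 3.79 and 3.49 FPKM), Ms4a2 (3.03, 1.8, 2.44 and 2.33) and Pecam1 (45.9, 41.5, 42.1 and 42.7).

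**Figure D2:**
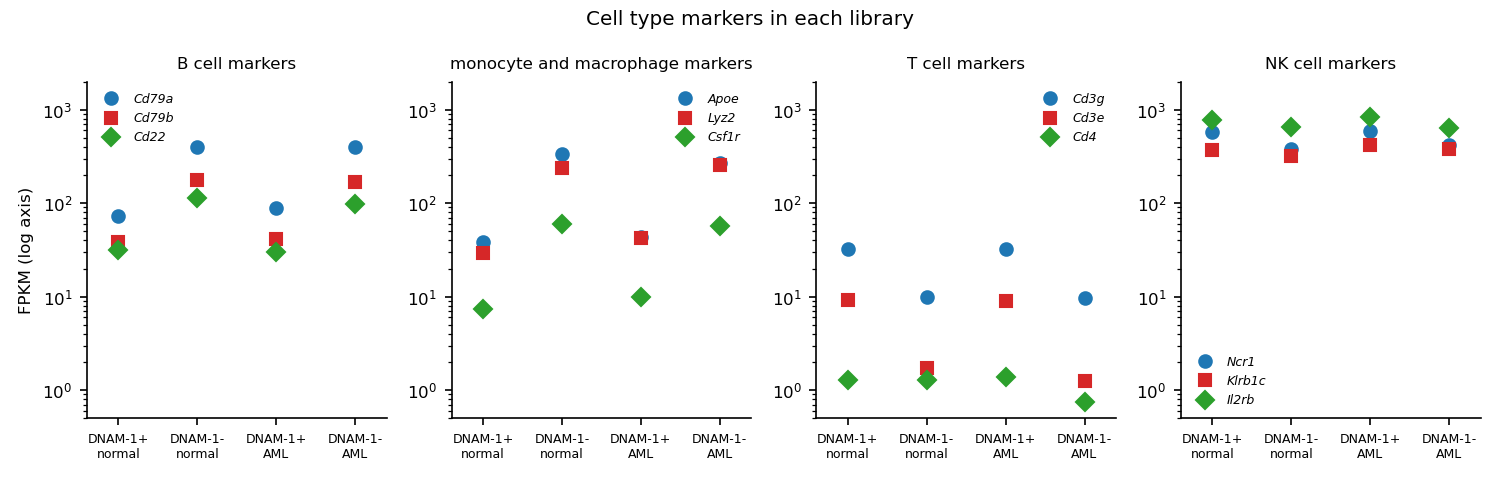
FPKM (log axis) of 3 markers each of B cells, monocytes and macrophages, T cells and NK cells in the 4 libraries, with each symbol standing for a gene in a single library. Cd79a is at 73 and 88 FPKM in the DNAM-1+ and at 395 and 399.7 in the DNAM-1- libraries, while Ncr1 lies between 383 and 597 in all 4.

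In DNAM-1+ cells at day 17 of leukaemia, the heat shock genes Hspa1b (15511; 35.3 to 3.97 FPKM from normal to AML spleen) and Hspa1a (193740; 14.4 to 1.67) were lower, and so were the interferon-stimulated genes Ifit3 (15959; 21.1 to 6.62), Oasl2 (23962; 5.74 to 1.74) and Rtp4 (67775; 35.7 to 15.6). The proliferation gene Mki67 was lower too (63.2 to 36.3). Eps8l1 (67425), an actin regulator, was higher (7.35 to 20.2), as were Fos (14281; 18.3 to 43.8), the phosphatase gene Dusp2 (13537; 77.8 to 142) and the chemokine gene Ccl4 (20303; 81 to 152). Of 8682 genes, 27 were at least 2-fold higher and 30 at least 2-fold lower in AML, and only 3 and 11 of these were protein-coding.

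Among protein-coding genes of DNAM-1+ cells the 8 highest log2 ratios were those of Eps8l1 (1.34), Fos (1.22), Spp1 (1.11), Oaz1 (0.91), Ccl4 (0.90), Blvrb (0.89), Dusp2 (0.86) and Fosb (0.82). The lowest was Amer2, at 13.1 FPKM in normal and listed at 0 in AML spleen, followed by Hspa1b (-2.87), Hspa1a (-2.53), Ifit3 (-1.54), Mid1 (-1.37), Oasl2 (-1.30), Tmsb15a (-1.24) and Rtp4 (-1.15). Over all gene types, all of the 8 highest (Mir7115, Snord65, Mir7087, Mir6516, Mir7090, Mir7052, Mir7037 and Mir7648) and 6 of the 8 lowest (Mir719, Snord95, Mir6916, Mir7036b, Snord47 and Mir1306) were small RNA genes, each listed at 0 in a library of the pair. The pseudogene Ubb-ps was at 18.9 FPKM in normal and listed at 0 in AML spleen.

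In DNAM-1- cells, Hspa1b was at 119 FPKM in normal and 10.3 in AML spleen, Hspa1a at 58.7 and 7.87, Rtp4 at 34.5 and 11.9, Ifit3 at 20.4 and 7.35, and Oasl2 at 16.1 and 5.41. Eps8l1 was at 8.67 and 22.8, Dusp2 at 98.4 and 150.3, Fos at 49.9 and 74.9, and Jchain at 103 and 206. Of 8808 genes, 17 were at least 2-fold higher and 35 at least 2-fold lower in AML, of which 2 and 17 were protein-coding. The highest protein-coding log2 ratios after Eps8l1 (1.30) were those of Cd209a (1.20), Jchain (0.99), Slpi (0.96), the linker histone gene H1f2 (0.85), Vkorc1 (0.74), Fam174c (0.68) and Tnfsfm13 (0.66). The lowest, after Hspa1b (-3.41), Hspa1a (-2.75), Rtp4 (-1.46) and Oasl2 (-1.42), were Oasl1 (-1.41), Ifit3 (-1.36), Oas2 (-1.22) and Ifi204 (-1.17). Over all gene types, all of the 8 highest (Mir7080, AF357399, Mir3572, Mir199a-1, Mir5119, Mir7682, Snora78 and Mir466i) and 7 of the 8 lowest (Mir546, Mir7213, Snord95, Snord38a, Snora61, Mir6910 and Snord32a) were small RNA genes.

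Across genes, the AML contrasts of the 2 subsets, which share no library, correlated with Pearson's r = 0.18 and Spearman's rho = 0.26 over 9074 genes and r = 0.403 over protein-coding genes. In both subsets 7 genes were at least 2-fold higher, against 0.11 for independent lists, 12 were at least 2-fold lower, against 0.15, and 10 went in opposite directions. Among protein-coding genes the counts were 2 (Eps8l1 and Cd209a), 8 and 0. The small RNA genes at least 2-fold in both were Mir5130, Mir7080, Mir199a-1, Snord87 and AF357399 upward, and Snord95, Mir5122 and Mir6990 among those downward. In the limma fit, with the subset as a block, 6 genes rose and 26 fell at day 17. The subsets may have come from the same mice, since the labels do not say, so this p does not measure the spread between mice. The call count rests on the setting. Fitted to protein-coding genes alone, limma called 26 genes higher and 81 lower, with 25 of the 32 main calls among them. Without its mean-variance trend 1 rose and 4 fell. The 32 main calls include small RNA genes such as Snord95 and Mir5130, which rest on few reads.

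Hspa1a fell by 2.64 on the log2 scale (SE 0.09, limma adjusted p = 0.000509, lower in 2 of 2 subsets) and Hspa1b by 3.14 (SE 0.13, adjusted p = 0.000714). These heat-inducible chaperone genes are near-identical copies that can share reads. Interferon-stimulated genes had a median log2 ratio of -0.49 in DNAM-1+ and -0.50 in DNAM-1- cells, and 12 of 39 tested members fell and 0 rose (31 and 0 adjusted over the list alone). These calls rest on the setting: over all genes 0 members fell without the mean-variance trend and 1 with a floor of 1 FPKM, while 20 fell with size factors or quantile normalization. Ifit3 (limma adjusted p = 0.00345), Rtp4 (0.00853), Oasl2 (0.0197), Oasl1 (0.0197) and Ifi204 (0.0377) were among the 12. Neutrophil markers moved in the same direction, with medians of -0.24 and -0.21 and 3 of 8 tested members falling adjusted over the list alone. Mid1, a ubiquitin ligase gene, fell (19.1, 19.6, 6.77 and 8.89 FPKM, in the order given above, adjusted p = 0.0143), while Eps8l1 (adjusted p = 0.00345), Dusp2 (0.0297) and H1f2 (0.0327) rose.

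Cell cycle genes had medians of -0.49 in DNAM-1+ and -0.22 in DNAM-1- cells at day 17. Over all genes 0 of 38 rose or fell, and 0 rose and 21 fell adjusted over the list alone. Mki67 was at 63.2, 22.7, 36.3 and 16.8 FPKM (limma adjusted p = 0.0899), Cenpe at 7.71, 2.56, 4.23 and 1.89 and Cdc20 at 12.3, 5.67, 10.3 and 3.43. Immediate early and stress genes had medians of 0.33 and 0.00, with 1 of 33 rising and 2 falling (9 and 5 adjusted over the list alone): Dusp2 rose and the Hsp70 genes fell, while Hsp90aa1 was at 111, 120.4, 87.7 and 80.1 FPKM (adjusted p = 0.0928).

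In every other list limma called 0 genes at day 17 over all genes. The CD11b-positive mature genes had medians of 0.12 and 0.14, with 6 rising and 1 falling adjusted over the list alone. Klrg1 was at 109, 98.9, 134 and 131 FPKM, Cx3cr1 at 35.5, 42.2, 43.8 and 53.1, Ly6c2 at 137, 159, 188 and 192 and Lgals3 at 23.3, 27.1, 17 and 18.7. NK lineage genes had medians of 0.09 and 0.14 (5 rising adjusted over the list alone), with Nkg7 at 464, 600.3, 663 and 665. Cytokines and chemokines had medians of 0.18 and 0.06 (4 rising adjusted over the list alone), with Ccl3 at 164, 249, 256 and 287 and Ccl5 at 5390.0, 4682, 6089 and 5552. Inhibitory receptors had medians of 0.15 and 0.08 (3 rising adjusted over the list alone), with Klra9 at 284, 218, 350.4 and 313. Chemokine receptors had medians of 0.16 and 0.01 (3 rising and 1 falling adjusted over the list alone), with Cxcr4 at 41.8, 64.5, 62 and 86. ILC1 genes had medians of 0.17 and 0.01, CD27-positive genes -0.06 and -0.06, activating receptors -0.02 and 0.06, cytotoxic genes 0.05 and 0.02, and exhaustion-associated genes 0.13 and 0.06. Medians of the remaining lists lay between -0.11 and 0.11 in both subsets. Adjusted over the list alone, 2 ILC1 genes and 1 glycolysis gene rose, 2 CD27-positive genes rose and 1 fell, 2 genes of IL-12, IL-18 and interferon receptors fell, and 1 gene each fell among cytotoxic, transcription factor and MYC genes. Of the 96 medians of 24 lists in 4 contrasts, 46 lay outside the central 95% of random lists, and 17 differed in sign from the list's mean (1 of the 46 among them). Independent lists and contrasts of unrelated genes would give 4.8. The contrasts share libraries, lists share members such as Il7r, and members may vary together, so the number due to chance is not known.

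Monocyte and macrophage markers had medians of 0.17 in DNAM-1+ and -0.21 in DNAM-1- cells, B cell markers 0.13 and -0.09, dendritic cell markers 0.29 and -0.05, plasma cell markers 0.21 and 0.17, T cell markers -0.07 and -0.03, and neutrophil markers -0.24 and -0.21. Leukaemia and myeloid progenitor markers had medians of 0.14 and 0.19, the latter reversing to -0.18 over the 3 members at 5 FPKM or more. Mpo (0.25, 0.26, 1.58 and 2.29 FPKM) and Ctsg (0.11, 0.11, 1.1 and 1.68), granule genes known from myeloid progenitors, were higher in the AML libraries and were named after their values were seen. At day 17 limma called 0 genes in these lists over all genes. Erythroid markers had medians of 0.19 and 0.00, with members from -0.13 to 2.07 in DNAM-1+ and from -1.61 to 0.23 in DNAM-1- cells. ILC2 and ILC3 markers had medians of 0.03 and 0.10, and limma called 0 genes in these 2 lists over all genes. Adjusted over the list alone, 3 neutrophil markers fell, 2 dendritic cell markers rose and 1 fell, and 1 leukaemia and progenitor marker rose and 1 fell. In the same way 1 plasma cell marker and 1 ILC2 and ILC3 marker rose.

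**Figure D3:**
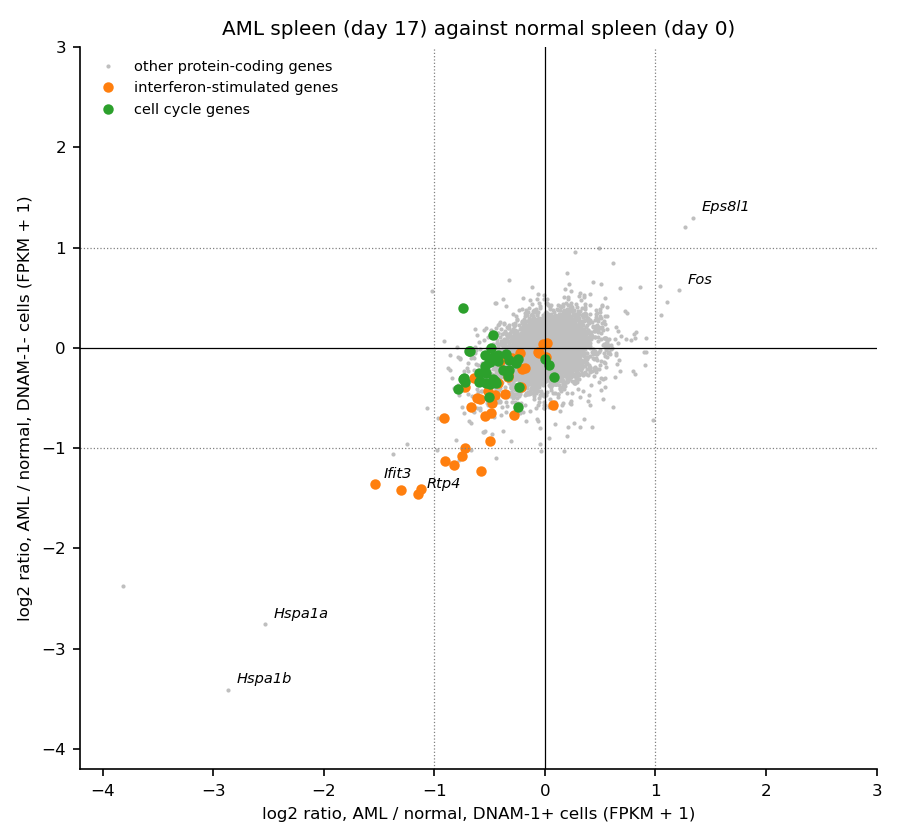
Log2 ratio of AML (day 17) to normal (day 0) spleen (FPKM + 1) in DNAM-1+ (horizontal axis) and DNAM-1- cells (vertical axis) for protein-coding genes at 5 FPKM or more in any library; each point is a gene, interferon-stimulated genes are orange, cell cycle genes green, and dotted lines mark a log2 ratio of -1 and 1. Hspa1b lies at -2.87 and -3.41, Ifit3 at -1.54 and -1.36, and Eps8l1 at 1.34 and 1.30.

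Whether leukaemia altered the DNAM-1 contrast itself could not be tested, because the interaction has no residual degrees of freedom. Leukaemia is also confounded with day in these libraries, here as in the AML contrasts above. A difference between the spleens therefore cannot be ascribed to leukaemia. The DNAM-1 contrast differed by at least 1 on the log2 scale in 99 of 9074 genes, of which 17 were protein-coding. Ccl4 was at 81 FPKM in DNAM-1+ and 151 in DNAM-1- cells of normal spleen, and at 152 and 134 in AML spleen. The largest protein-coding differences of the log2 ratio, AML minus normal spleen, were those of Ms4a4a (1.70), Amer2 (-1.44), Slirp (1.21), Pradc1 (1.21), Ms4a6d (1.20), Gtpbp8 (-1.18), Cdk1 (-1.14) and Rhox8 (1.10). The 8 largest over all gene types were Snord65, Snord38a, Mir7036b, Mir7052, Ubb-ps, Mir719, Snord73a and Snord32a, all listed at 0 in at least 1 library.

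**Figure D4:**
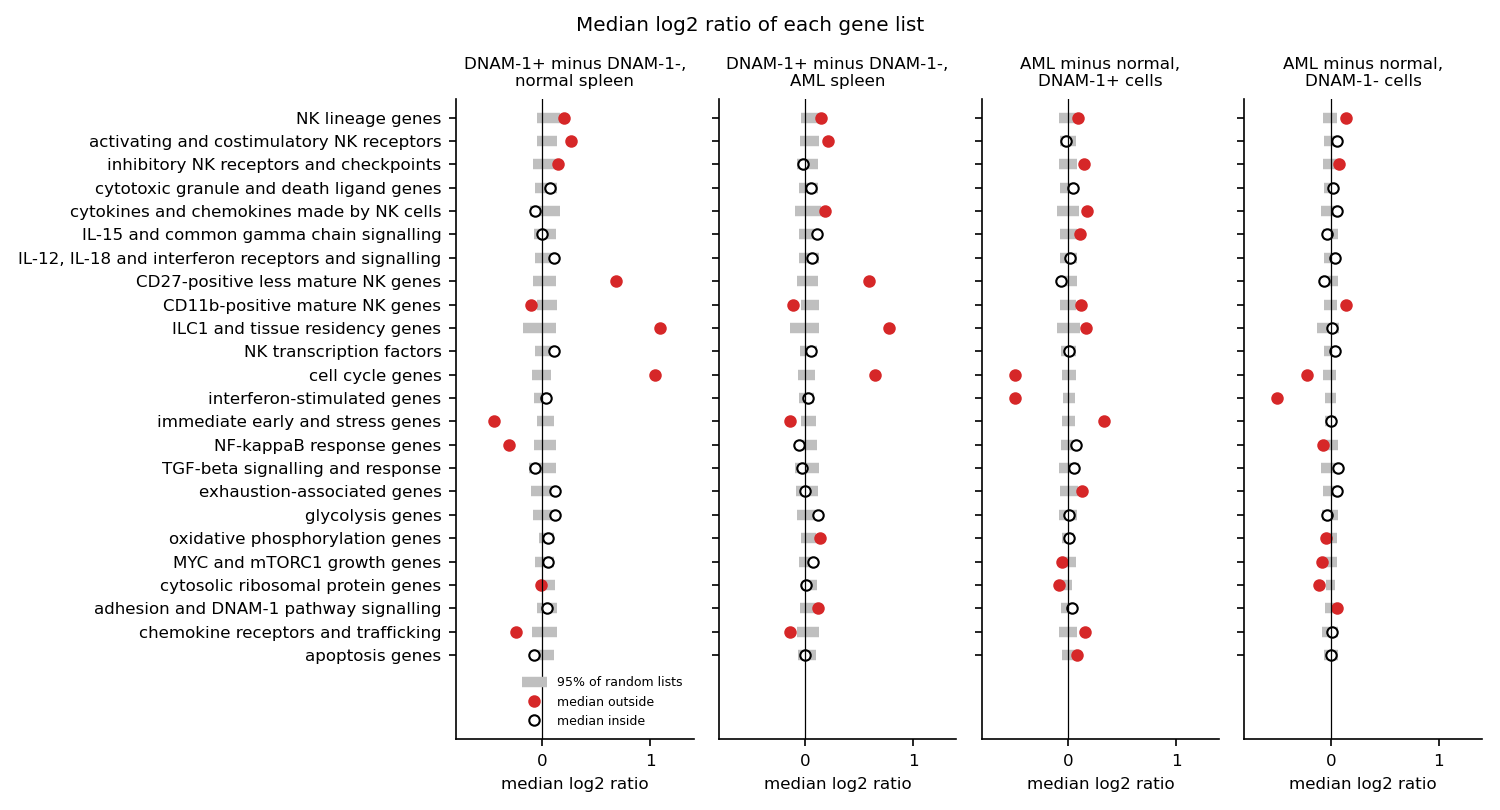
Median log2 ratio of each of 24 gene lists in the 4 contrasts (points; filled red where outside the grey bar, which spans the central 95% of 10000 random lists of like size and expression). Cell cycle genes lie at 1.05 and 0.65 in the DNAM-1 contrasts, and interferon-stimulated genes at -0.49 and -0.50 in the AML contrasts.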

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

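All tests of explanations below were chosen after the results were seen. Monocyte and macrophage markers had a median log2 ratio of AML to normal of 0.17 in DNAM-1+ and -0.21 in DNAM-1- cells; this difference was not tested. Another 12 named genes, none of them protein-coding, were at least 2-fold in opposite directions in the 2 spleens or the 2 subsets, and these differences were not tested either. Their highest levels were 18.9 FPKM for Ubb-ps, 12.4 for Mir719, 10.5 for Snord65, 9.83 for Snord38a, 8.81 for Mir6516, 8.78 for Mir466i, 8.05 for Mir7036b, 7.58 for Mir7052, 7.46 for Snord32a, 7.27 for Snora78, 6.77 for Snord73a and 6.29 for Mir7648.

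B cell, monocyte and plasma cell genes were higher in the DNAM-1- library of both spleens, and other cells within that sort are a candidate explanation. If a lower share of NK cells raised the genes of every other cell type alike, neutrophil markers would move with B cell markers. With a pseudocount of 0.1, the median of 8 neutrophil markers lay above that of B cell markers in both spleens. The log2 excess was 1.07 in AML spleen (95% of resampled members 0.69 to 1.27) and more in normal spleen (1.22 to 1.81). This argues against such a lower share as the whole cause but does not exclude it, since the intervals cover list members, not libraries. RNA of B cells would raise their markers by a like factor, and 100% of the 13 B cell markers lay within 0.5 of their median in both spleens (-2.28 and -2.04 with a pseudocount of 0.1), against 59.4% and 64.6% of 229 other protein-coding genes lower in both, which is consistent with B cells in the DNAM-1- sort, where Cd74 reached 1458 FPKM. For monocytes and macrophages the lower share was 28.6% of 14 markers, although 100% of them had a log2 ratio of -0.5 or lower in both spleens. The list joins more than 1 cell type, and admixture of several types need not give a common ratio. The test therefore cannot decide between admixed cells and expression by NK cells. The labels name no gate that would remove these cells.

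CD27-positive, ILC1 and cell cycle genes were higher in the DNAM-1+ library of both spleens, and dilution of NK RNA in the DNAM-1- library could do this to every NK gene alike. The median exceeded that of NK lineage genes by 0.48 in normal (95% of resampled members 0.05 to 0.83) and 0.45 in AML spleen (0.07 to 1.21) for CD27-positive genes, and by 0.85 (0.63 to 1.01) and 0.51 (0.33 to 0.78) for cell cycle genes. These intervals cover list members, not libraries, and single NK lineage genes ranged from -0.37 to 1.28 in normal and from -0.12 to 1.27 in AML spleen. The excess argues against dilution as the whole cause for these lists but does not exclude it. For ILC1 genes the excess was 0.89 (-0.25 to 1.20) and 0.63 (-0.05 to 1.29), which leaves it open. Were T cells in the DNAM-1+ sort the source, Cd4, Cd8a, Cd8b1 and Cd5 might be higher there. The log2 ratio of their sum was at most -0.13, but the sums were only 5.46 to 9.06 FPKM in the 4 libraries. That is below the level set for the test to count against T cells, so it does not decide. T cells with or without these genes remain possible, and Cd3d, Cd3e and Cd3g summed to 54.5 against 16.9 FPKM in normal spleen. A difference of NK stage was not tested and remains open.

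Interferon-stimulated and Hsp70 genes were lower at day 17 in both subsets. A loss of another cell type would lower its markers as far. The lowest median of a cell type in both subsets, that of neutrophils, was -0.21 where it moved least, against -0.49 for interferon-stimulated genes. Its excess over theirs was 0.25 in DNAM-1+ (95% of resampled members -0.09 to 0.43) and 0.28 in DNAM-1- cells (0.06 to 0.58), which leaves a loss of neutrophils open. Erythroid markers overlapped in DNAM-1- cells (0.50, -0.06 to 0.84). Monocyte, dendritic, B, plasma and T cell markers lay above beyond that spread in both subsets. B cell markers did so by 0.62 (0.47 to 0.76) and 0.40 (0.28 to 0.58). This argues against a loss of those cells as the whole cause, though the added 1 FPKM limits the fall of low markers. Leukaemia and progenitor markers lay above too, but normal spleen held no transplanted leukaemia cells that could be lost. For Hspa1a and Hspa1b, shared reads cannot account for the fall, since the log2 ratio of their sum was -2.93 in DNAM-1+ cells. With a pseudocount of 0.1, no cell type with at least 5 measured markers had a median nearer to their sum than 2.86 (95% of resampled members 2.27 to 2.95). This argues against a loss of any such type as the whole cause. It does not exclude one, since a list can join more than 1 cell type and the interval covers list members, not libraries. Handling that differed between the days would move stress genes together; the immediate early median was 0.33 in DNAM-1+ and 0.00 in DNAM-1- cells, which leaves handling open, as does its confounding with day. A response of NK cells to leukaemia may also account for the pattern and was not tested.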

How the results depend on the processing

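The alternative with protein-coding genes alone, and all alternatives for the count of genes whose DNAM-1 contrast differed between spleens, were chosen after the data were seen; the rest were fixed in advance. With 1 library per group no alternative measures the spread between mice, and shallow depth limits genes of low level and short length, whose values step by single reads. Of the list medians under alternatives, 604 stayed within 1.5-fold, 7 moved and 1 that lay outside the central 95% of random lists reversed. Among the 604, 11 medians inside that central range changed sign. A 1.5-fold change is larger than many of the medians themselves, such as the 0.20 and 0.15 of NK lineage genes in the DNAM-1 contrasts. Small medians could vanish and still count as stayed, so this count says little about them. Of the log2 ratios of named genes 4502 stayed and 378 moved, and 30 of the former, neither called by limma nor 2-fold, changed sign. Of limma calls per list 1020 stayed and 132 moved. Those that moved included 30 without trend, 27 with a floor of 20 FPKM, 24 with quantile normalization and 22 with protein-coding genes alone. A count of 0 that remained 0 was also taken as stayed. For AML against normal most lists held no call over all genes, so the 1020 say little about how stable calls were. The list counts printed above are therefore those of the main setting unless another is named. Median-ratio size factors, upper quartile scaling and leaving out cell type markers left every 2-fold count and shared or opposite count within 1.5 times its main value. Correlations stayed within 0.1, a wide margin for the AML r of 0.18. The size factors lay between 0.993 and 1.009, so they could change little. Without the markers, 318 (normal) and 250 (AML spleen) genes were still at least 2-fold lower in DNAM-1+ cells, against 354 and 282. Leaving them out therefore does not test for admixed cells. For the values below, floors change the number of genes tested by construction, and for every other setting the cause was not tested.

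With a pseudocount of 0.1 the DNAM-1 contrasts correlated with r = 0.559 and 86 genes were higher in both, and the AML contrasts with r = 0.0594. With a pseudocount of 5, genes at least 2-fold higher in DNAM-1+ cells numbered 39 in normal spleen and 40 in AML spleen, where 161 were lower; 18 and 17 were lower in AML in DNAM-1+ and DNAM-1- cells. The DNAM-1 contrasts then shared 14 higher and 148 lower genes with 2 opposite, the AML contrasts 1 higher, 4 lower and 1 opposite, 52 genes differed in their DNAM-1 contrast, and limma called 17 genes lower in AML.

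With a floor of 1 or none, 221 genes were higher and 589 lower in DNAM-1+ cells of normal spleen, 169 and 444 in AML spleen, and 108 and 102 (DNAM-1+) and 73 and 119 (DNAM-1-) in AML. The DNAM-1 contrasts shared 82 higher genes with 32 opposite, the AML contrasts 18 higher and 26 lower with 25 opposite. The DNAM-1 contrast differed in 309 genes with a floor of 1 and 325 with none, where r was 0.632. With a floor of 1 limma called 5 genes lower in AML. With a floor of 20 these counts were 21 and 143, 20 and 110, 3 and 3, and 3 and 7. The DNAM-1 contrasts then correlated with r = 0.914 and shared 18 higher and 114 lower genes with 0 opposite, the AML contrasts with r = 0.465, 1 higher, 4 lower and 0 opposite, and 9 genes differed. limma called 434 genes lower in DNAM-1+ cells, and 18 higher and 51 lower in AML.

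As TPM, the floor of 5 admits genes of lower FPKM and the added 1 stands for less than 1 FPKM, so that both settings change at once. Then 235 genes were higher and 571 lower in DNAM-1+ cells of normal spleen, 178 and 450 in AML spleen, and 91 and 89 (DNAM-1+) and 57 and 92 (DNAM-1-) in AML. The DNAM-1 contrasts correlated with r = 0.600 and shared 109 higher genes with 26 opposite, the AML contrasts shared 17 higher and 28 lower with 24 opposite, and 284 genes differed. Among protein-coding genes 3 were higher and 11 lower in AML in DNAM-1+ cells, and 2 and 17 in DNAM-1- cells. Of the protein-coding genes at least 2-fold apart, 21.4% and 10.5% were thus higher, against 47.4% and 32.7% of such genes of all types. The DNAM-1 contrasts then correlated with r = 0.895 with 0 opposite, the AML contrasts with r = 0.403 with 2 higher in both and 0 opposite, 17 genes differed, and limma called 26 genes higher and 81 lower in AML.

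limma called 18 genes higher and 73 lower in AML with size factors, and 33 and 83 with quantile normalization, and each set held all 32 genes of the main setting. Without trend it called 1 and 4 in AML, and 321 higher in DNAM-1+ cells, of 1427 subset calls 826 being shared. The median of ILC1 genes in normal spleen was 0.48 with a pseudocount of 5. Plasma cell markers had medians of -2.49 and -2.09 with a pseudocount of 0.1 and -0.44 and -0.54 with 5. With members at 5 FPKM or more, dendritic cell markers had medians of -1.68 and -1.51, and leukaemia and progenitor markers reversed to -0.18 in the AML contrast of DNAM-1- cells, where 3 members remained.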

Other observations

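The count by gene type was chosen after the data were seen. Small RNA genes made up 24 of the 27 genes at least 2-fold higher in AML in DNAM-1+ cells and 15 of 17 in DNAM-1- cells. Snord95 was at 10.2 and 10.5 FPKM in the normal libraries and listed at 0 in both AML libraries (limma adjusted p = 0.017). Mir5130 was at 1.82, 3.23, 8 and 12.9 FPKM in the order DNAM-1+ normal, DNAM-1- normal, DNAM-1+ AML and DNAM-1- AML (adjusted p = 0.0144). Amer2 was at 13.1, 4.18, 0 and 0 FPKM in that order (adjusted p = 0.0783). The smallest step of microRNA values, taken as 1 read, was 5.02 FPKM at 58 nt and 1.97 at 92 nt. Snord95 and Mir5130, as small RNA genes, thus rest on few reads, and their limma p-values do not make these changes firm.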
